A study of Mus musculus with 10 samples.

How the data were processed

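RNA was sequenced from 4 libraries of mouse embryonic stem cells of the E14 line that carry a degradable form of the histone chaperone NPM1. Per the labels, the cells were grown with leukemia inhibitory factor, 1 µM of the MEK inhibitor PD0325901 and 3 µM of the GSK3 inhibitor CHIR99021, held in G1 and released for 12 h, with auxin (2 libraries) or without it (2 libraries). Auxin triggers the destruction of a protein that carries an auxin-inducible degron. Polyadenylated RNA was converted to strand-marked libraries with dUTP in the second strand and read as 100 bp pairs, per the labels. H3K27me3, the histone mark set by Polycomb repressive complex 2, was mapped by ChIP-seq in 1 sample at 6 h without auxin and by CUT&RUN in 1 control sample at 12 h. The input, IgG, auxin and auxin with PRC2 inhibitor samples of these assays were not analysed here, so H3K27me3 itself was not compared between conditions.

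The deposited table holds raw fragment counts per gene name for 33006 genes. Per the file headers, the authors counted the fragments with featureCounts 1.6.3 over exons on the reverse strand with an mm10 annotation, and the submitters' processing notes name STAR 2.6.1d for alignment. Counts used strand, so antisense neighbours were kept apart, but reads shared between near-identical gene copies were not resolved, which bears on the Zscan4 and Usp17l families among the genes typical of 2-cell embryos. The submitters' processing notes name Bowtie2 2.4.1 and MACS2 2.1.1 for the chromatin libraries and list the builds mm10 and dm6. Each deposited peak list gives a score, a fold enrichment, a −log10 p and a −log10 q per broad peak, as the authors' peak caller wrote them from 1 sample without pooling. The control library and the cutoff behind the peaks are not given in the sources used here. The smallest −log10 q was 1.02 in the ChIP-seq list and 1.00 in the CUT&RUN list. These peak values were used only to describe or filter peaks within a list. Read depth of the chromatin libraries is unknown from the peak lists.

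Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, the default expression filter, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05, two-sided), with auxin against without and no block for the replicate number. The filter left 13522 genes. Standard errors of log2 fold changes were taken as the absolute fold change over the square root of F. Levels are CPM values, counts divided by TMM-scaled library sizes, as mean ± SD of 2 libraries, and fold changes are 2 raised to the fitted log2 value. Replicate libraries differed by more than counting noise (chi-square per degree of freedom of 3.86 without auxin and 11.1 with auxin), so none was treated as a repeat deposit. No label says whether the replicates were separate cultures, and p-values then measure only the spread between these libraries, which may be technical. In counts simulated from these libraries with 200 changed genes, edgeR recovered 90% of 100 genes changed by 1 on the log2 scale. It recovered 56% of 100 genes changed by 0.5, with 10 false calls among 13282 unchanged genes. A further small set, shifted by 0.5, was left out of these counts. The simulation gave both groups the same dispersion and changed far fewer genes than the 3723 called in the data. These rates may therefore not hold for these libraries, whose noise differed between groups.

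There were 30 gene lists, fixed with the tests and the rule for named genes before the data were examined. They cover Polycomb repressive complexes 1 and 2, histone chaperones, naive, core and formative pluripotency, germ layers and extraembryonic lineages, Hox and other developmental transcription factors, germline, imprinted and 2-cell-like genes, cell cycle phases, ribosomal proteins and ribosome biogenesis, glycolysis, sterol synthesis, stress pathways, p53, NRF2, Wnt, MAPK, interferon and aryl hydrocarbon receptor (AhR) targets, and fibroblast markers. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists. The test was repeated with an estimated correlation, where camera uses the few residual degrees of freedom of 4 libraries and has little power. A call lost there cannot tell correlated genes from a weak test, unless the estimate is at or below the preset value. fry in limma tested whether the genes of a list moved, on balance, one way. List medians were also set against 10000 random lists matched on mean expression, or on mean expression and annotated length. Only the matching of marked genes on expression was planned. The matching on length and that of the lists were chosen after the fold changes were seen, and what they would show for the marked and MAPK genes was written down before these comparisons were run. The matching was checked on simulated fold changes.

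A gene was called H3K27me3-marked when the window of 1 kb on either side of its 5′ end, from the coordinates in the count table (mm10), overlapped a peak of both lists (bedtools 2.31.1, at least 1 bp). Marked and other tested genes were compared with Fisher's exact test (scipy 1.17.1), and within expression deciles with a Mantel-Haenszel test (statsmodels 0.14.6). Overlap of peak lists was set beside 100 random placements on the same chromosome, and 95% intervals of shares are exact Clopper-Pearson intervals that cover counting error only. Of the 33006 genes, 32968 had a single placement and 38 were left out of position-based steps.

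Named genes were Npm1, the 8 called genes with the largest change in each direction (mean of at least 1 CPM, both auxin libraries on the same side of both others, predicted and RIKEN names left out), up to 2 called members of each list with the smallest p in each direction, and up to 5 called marked genes in each direction. Together these were 103 genes. Some of these genes, and a gene under one of the widest peaks, are not reported here. Other genes are named where a count is small, and were then chosen after their values were seen. Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, other expression filters, the replicate number as a block, each library left out, other definitions of marked genes and of overlap, and a test against a minimum change of 0.5, the last chosen after seeing the data. With 1 library left out, the lone library of its group is assumed to vary like the others. Library totals ran from 13353446 to 16046290 counts, and genes near 1 CPM rest on few fragments, so their fold changes are imprecise.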

Results

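The series asks what the loss of NPM1, a histone chaperone of the nucleolus, does to repressed chromatin and to transcription as mouse embryonic stem cells pass through S phase. RNA was measured 12 h after release from G1 in 2 libraries without auxin and 2 libraries with auxin, which removes the degron-tagged NPM1 protein. The libraries held 14789851 and 15183126 counts without auxin, and 13353446 and 16046290 with auxin. Mitochondrial transcripts took 4.06% and 3.52% of the counts without auxin and 4.96% and 3.46% with auxin. The most abundant feature, Gm26924, took 1.76% and 2.07% without auxin and 2.15% and 1.07% with auxin. H3K27me3 peaks of control cells came from 1 ChIP-seq sample (6 h, 41159 peaks) and 1 CUT&RUN sample (12 h, 66242 peaks).

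The degron acts on the protein, so the Npm1 transcript need not fall and does not check the labels. Npm1 (chromosome 11, 33152287 to 33163206, mm10, minus strand) stood at 1005 ± 75.6 CPM without auxin and 805 ± 53.8 CPM with auxin (SD, n = 2). It fell by 0.32 on the log2 scale (SE 0.06, edgeR quasi-likelihood adjusted p = 0.00337). Its raw counts were 15063 and 14030 without auxin, and 11429 and 12907 with auxin.

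Auxin changed the transcript level of many genes by small amounts and of a few by large ones. Of 13522 genes tested, 1759 were higher and 1964 were lower with auxin. The change exceeded 1 on the log2 scale for 382 of the higher genes and 136 of the lower genes. The steepest rises were in targets of the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor that senses indoles and aromatic compounds. The steepest falls were those of Spry4 and Etv4, both on the list of MAPK response genes.

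**Figure D1:**
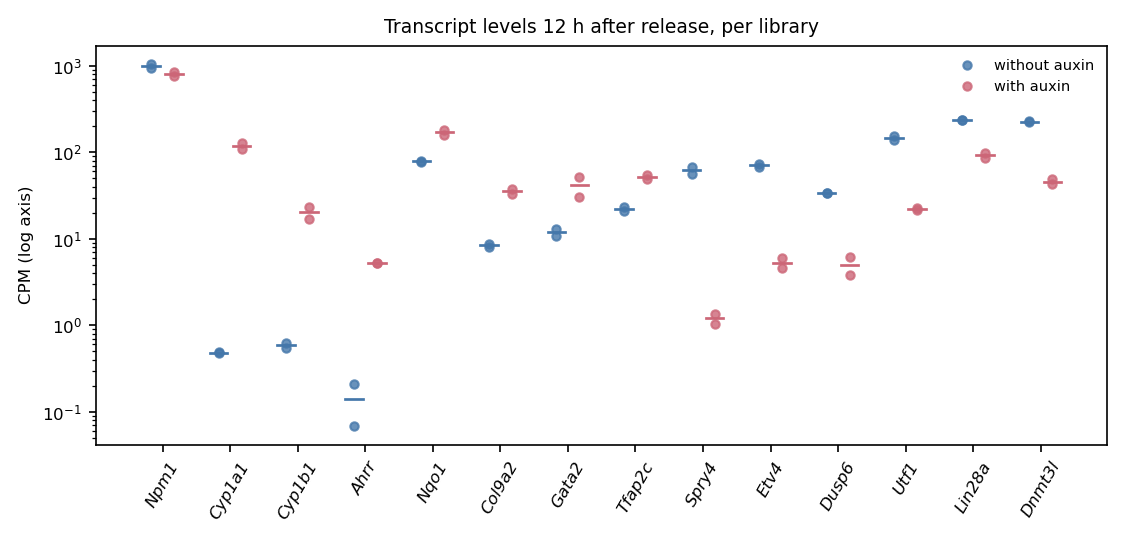
Library-size-scaled counts (CPM, log axis) of 14 named genes in the 4 RNA libraries, blue without auxin and red with auxin, with points for libraries and bars for the mean of 2. Cyp1a1 rose from 0.483 to 119 CPM and Spry4 fell from 62.3 to 1.20 CPM, while Npm1 moved from 1005 to 805 CPM.

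Cyp1a1, a xenobiotic-metabolizing cytochrome P450, rose 241-fold, from 0.483 ± 0.0121 to 119 ± 14.5 CPM (log2 fold change 7.91, SE 0.18, edgeR adjusted p = 5.28e-10). Cyp1b1 rose 33.7-fold to 20.2 ± 4.80 CPM (adjusted p = 6.67e-07). Ahrr, the AhR repressor and itself an AhR target, rose to 5.23 CPM (log2 fold change 5.16, SE 0.41), from only 3 and 1 fragments in the libraries without auxin. Of 7 AhR targets tested, 4 rose and 3 were not called (5 rose when adjusted over the list alone). The fourth was Nqo1, which the NRF2 list also holds (2.16-fold, adjusted p = 2.40e-06). The list stood above other genes by camera (adjusted p = 0.000320), a call lost with an estimated correlation (adjusted p = 0.419 with an estimated correlation). Other large rises were those of Lrrc15 (7.16-fold), the T cell coreceptor Cd4 (10.5-fold), Mal (6.41-fold), the cytokine receptor Csf3r (6.39-fold) and Trim43a (5.89-fold), all from under 3 CPM without auxin.

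Spry4, an inhibitor of receptor tyrosine kinase signalling, fell 50.8-fold, from 62.3 ± 8.29 to 1.20 ± 0.236 CPM (log2 fold change −5.67, SE 0.17, edgeR adjusted p = 4.68e-09). Etv4, a transcription factor induced by ERK, fell 13.2-fold, and Dusp6, the ERK phosphatase, fell 6.93-fold. Of 19 tested genes of the MAPK response, 12 fell, 1 rose and 6 were not called (13 fell and 1 rose when adjusted over the list alone), with a median log2 fold change of −0.53. The list stood below other genes by camera (adjusted p = 3.97e-05), which did not hold under the alternative (adjusted p = 0.398 with an estimated correlation). The exception was Jun (log2 fold change 0.28, adjusted p = 0.0473), whose call was lost without replicate 1 (adjusted p = 0.131) or replicate 2 (0.120) of the libraries without auxin, without auxin replicate 1 (0.256), with RLE factors (0.0501) and with DESeq2 (0.234). The other large falls were Enox1 (9.63-fold), Chrna9 (7.63-fold), Aire (7.16-fold), Hdhd1a (6.88-fold) and Utf1. Aire overlaps the 5′ end of Dnmt3l on the opposite strand of chromosome 10, and both fell.

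Most core pluripotency genes fell, and naive pluripotency genes went both ways. Of 12 core pluripotency genes, 9 fell and 3 were not called (9 fell when adjusted over the list alone), among them Utf1, a chromatin-associated stem cell factor (6.63-fold, from 146 ± 9.81 to 22.1 ± 0.573 CPM), and the RNA-binding protein Lin28a (2.57-fold, adjusted p = 3.08e-07). Of 11 genes of the formative and primed states, 6 fell and 5 were not called (6 adjusted over the list alone), including the DNA methylation factors Dnmt3l (4.91-fold) and Dnmt3b (1.90-fold). Of 17 naive pluripotency genes, 6 rose, 8 fell and 3 were not called (7 and 8 when adjusted over the list alone). Prdm14 rose 1.64-fold and Nanog 1.25-fold, while Nr0b1 fell 1.65-fold and Tdh fell 1.48-fold. Camera placed the core list (adjusted p = 1.51e-05) and the formative list (adjusted p = 0.00120) below other genes, and neither call held (adjusted p = 0.419 and 0.398 with an estimated correlation). For the formative list the estimate was −0.021, below the preset 0.01, so a higher correlation was not the reason. The naive list did not stand apart (adjusted p = 0.618), and its median of −0.07 and its test had the opposite sign to its mean of 0.01.

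Most tested genes on the ribosome and cell cycle lists were called lower, by small amounts in the list medians. Of 79 cytosolic ribosomal protein genes, 73 fell and 6 were not called (75 fell when adjusted over the list alone), with a median log2 fold change of −0.23. Rps13 (log2 fold change −0.38) and Rpl8 (−0.34) had the smallest p. Of 54 ribosome biogenesis genes, 46 fell and 8 were not called (53 adjusted over the list alone), with a median of −0.33. Heatr1, a factor for ribosomal RNA transcription and processing, fell 1.47-fold, and the nucleolar protein Nolc1 fell 1.45-fold. Random lists matched on expression had a median of −0.16 for ribosomal proteins (central 95%, −0.21 to −0.11) and −0.12 for ribosome biogenesis, so equally abundant genes also had negative values. Camera gave an adjusted p of 3.17e-16 for ribosomal proteins and 3.84e-16 for ribosome biogenesis, and neither held (adjusted p = 0.398 and 0.419 with an estimated correlation). Of 40 G1/S genes, 24 fell and 16 were not called (29 adjusted over the list alone), including the DNA polymerase subunit Pola1 (1.44-fold) and the replicative helicase subunit Mcm7 (1.29-fold). Of 40 G2/M genes, 29 fell, 1 rose and 10 were not called (33 fell and 1 rose adjusted over the list alone), including the proliferation marker Mki67 (log2 fold change −0.38) and the spindle checkpoint kinase Bub1b (1.29-fold). The riser, Pttg1 (adjusted p = 0.0373), lost its call without replicate 1 without auxin (0.261), without auxin replicate 1 (0.0585), without auxin replicate 2 (0.0679) and with DESeq2 (0.183). Random lists matched on expression had medians of −0.09 for G1/S and −0.10 for G2/M, against −0.25 and −0.26 for the lists. Camera gave adjusted p values of 2.81e-08 for G1/S and 1.39e-08 for G2/M. Both calls were lost with an estimated correlation (adjusted p = 0.398 for each). For G2/M the estimate was 0.0097, close to the preset 0.01, so a higher correlation was not the reason. By fry, adjusted p was 0.0119 for ribosomal proteins and G2/M, and 0.0178 for ribosome biogenesis and G1/S.

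More than 9 of the tested histone chaperones, the class to which NPM1 belongs, were called lower. Of 22 tested, 13 fell and 9 were not called (17 fell when adjusted over the list alone), with a median of −0.25, against −0.12 in random lists matched on expression. The chromatin remodeller Atrx fell 1.48-fold and nucleolin (Ncl) 1.35-fold. The camera call (adjusted p = 2.62e-05) was lost when the correlation was estimated (adjusted p = 0.481 with an estimated correlation). Of 21 genes of glycolysis and hypoxia, 14 fell, 2 rose and 5 were not called (15 and 2 adjusted over the list alone). Pdk1 fell 3.59-fold, and the glycolytic enzyme Eno1 fell 1.43-fold, while Vegfa (1.99-fold) and Hk1 (1.34-fold) rose. Camera placed this list below other genes (adjusted p = 0.000363), again without an estimated correlation (adjusted p = 0.419 with an estimated correlation).

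Some developmental regulators rose with auxin, and more were not called. Of 23 Hox genes tested, 10 rose and 13 were not called (12 rose when adjusted over the list alone), all 23 had a positive log2 fold change, and the median was 0.78. Hoxc12 rose 1.91-fold, to 19.5 ± 1.01 CPM, and Hoxc4 rose 2.18-fold, to 7.14 ± 0.0177 CPM. Of 55 other developmental transcription factors, 15 rose, 2 fell and 38 were not called (15 and 3 adjusted over the list alone), with Msx1 (4.90-fold) and Onecut2 (3.73-fold) among the risers. The fallers were Foxd3 (1.44-fold) and Alx1 (adjusted p = 0.0189). Alx1 lost its call without replicate 2 without auxin (0.129), without auxin replicate 1 (0.0900) and with DESeq2 (0.135). Of 14 trophectoderm genes, 6 rose, 1 fell and 7 were not called (7 and 1 adjusted over the list alone). Gata2 (3.48-fold) and Tfap2c (2.35-fold) rose, and Tead4 fell by 0.38 on the log2 scale. Of 13 Wnt targets, 7 rose, 1 fell and 5 were not called (8 and 1 adjusted over the list alone), with Rnf43 (2.51-fold) and Dkk1 (1.95-fold) among the risers and the cyclin Ccnd1 the faller (1.44-fold).

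DESeq2 called fewer of these genes higher, with 3 Hox genes, 9 developmental factors and 4 Wnt targets. Random lists matched on expression had medians of 0.18 for Hox genes, 0.16 for developmental factors, 0.07 for trophectoderm and −0.02 for Wnt targets. Camera called these lists higher, with adjusted p values of 3.44e-05 for Hox genes, 0.00273 for developmental transcription factors, 0.0118 for trophectoderm and 0.0430 for Wnt targets. None held with the other setting (adjusted p = 0.525, 0.685, 0.685 and 0.419 with an estimated correlation, in that order). For Wnt targets the estimate was −0.060, below the preset 0.01, so a higher correlation was not the reason. Without auxin replicate 2, the developmental list (adjusted p = 0.0634), the trophectoderm list (0.0670) and the Wnt list (0.0503) were no longer called. The Wnt list was also lost without replicate 1 (0.0650) or replicate 2 (0.0997) of the libraries without auxin, with upper-quartile factors (0.0532) and with the filter of at least 1 read in any library (0.130). fry, which tests each list against no change, called 11 of the 14 lists that camera called with the preset correlation. These included the Wnt list (adjusted p = 0.0119) but not the Hox (0.123), developmental (0.248) or trophectoderm (0.134) lists.

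**Figure D2:**
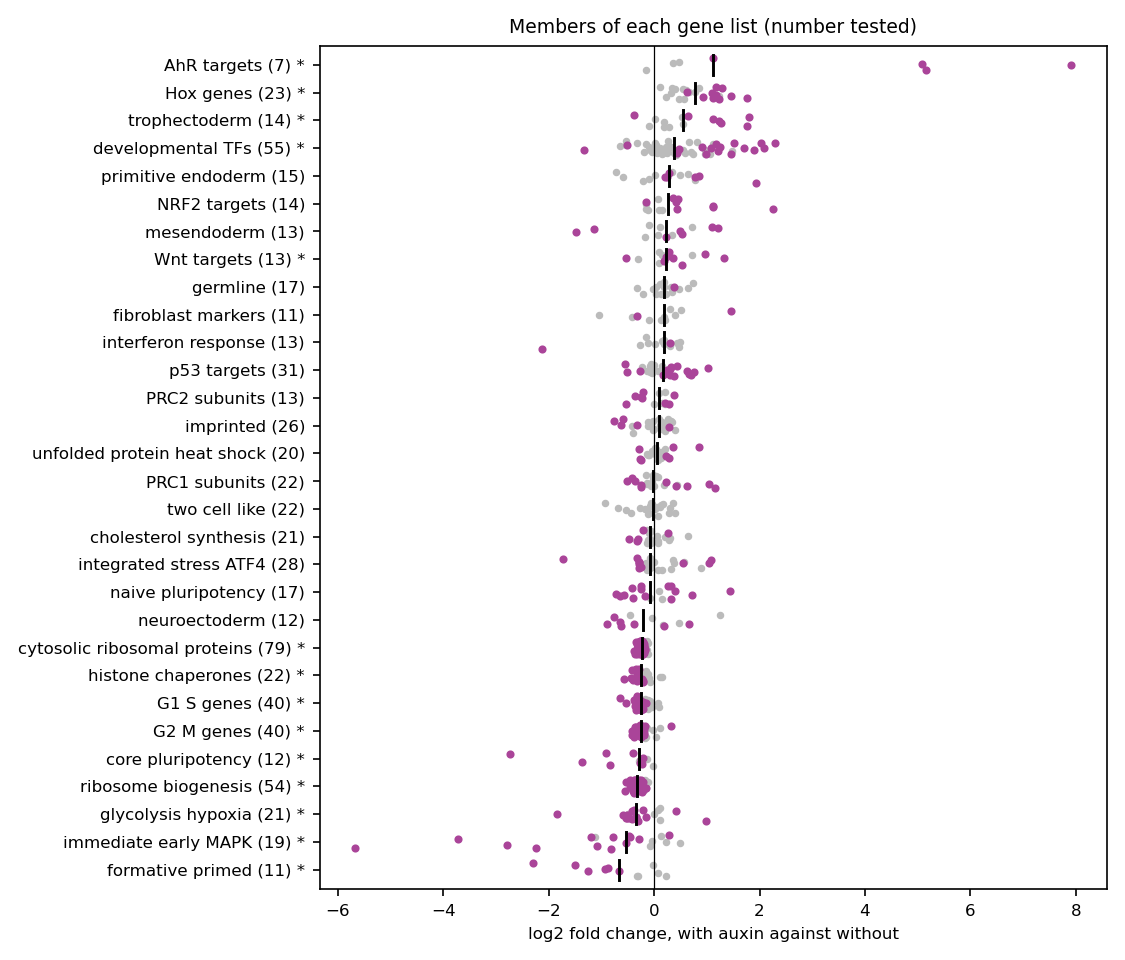
Log2 fold change of each tested member of the 30 gene lists (x axis), with auxin against without, ordered by the list median (black bar). Purple points passed an edgeR adjusted p of 0.05, grey points did not, and an asterisk marks the 14 lists called by camera with the preset correlation. Hox genes had a median of 0.78 and formative pluripotency genes a median of −0.66.

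The subunits of the Polycomb complexes moved both ways. Of 13 PRC2 genes, 3 rose, 5 fell and 5 were not called (4 and 5 adjusted over the list alone). The cofactor Jarid2 fell 1.45-fold and Eed, a core subunit, fell 1.29-fold. Rbbp4, Ezh2 and Rbbp7 also fell, and Mtf2, Ezh1 and Phf1 rose, with Phf1 and the last 3 fallers named after their values were seen. Mtf2 (adjusted p = 0.0133) lost its call without replicate 1 (0.0604) or replicate 2 (0.0534) of the libraries without auxin and without auxin replicate 1 (0.0833). Ezh1 (adjusted p = 0.0258) lost it without replicate 2 without auxin (0.168), without auxin replicate 2 (0.0979) and with DESeq2 (0.149). Of 22 PRC1 genes, 5 rose, 5 fell and 12 were not called (5 and 5 adjusted over the list alone). Phc1 (1.43-fold) and Kdm2b (1.34-fold) fell, and Bmi1 (1.55-fold) rose. Others, named after their values were seen, were L3mbtl2, Cbx7 and Rnf2 among the fallers and Cbx8, Pcgf3 and Scmh1 among the risers. DESeq2 called 1 PRC2 gene and 3 PRC1 genes higher. Neither list stood apart (camera adjusted p = 0.804 and 0.836), and the PRC2 median of 0.10 had the opposite sign to its mean (−0.01) and test, as had the PRC1 mean of 0.08 to its median (−0.02) and test.

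The peak lists show where H3K27me3 lay in control cells, from 1 sample each, so differences between them have no replicate check. ChIP-seq peaks had a median width of 445 bp and covered 23.3 Mb, while CUT&RUN peaks had a median width of 862 bp and covered 86.4 Mb. Of the ChIP-seq peaks, 52.0% (95% interval 51.5 to 52.5%) overlapped a CUT&RUN peak, against 5.59% on average over 100 random placements. Of the CUT&RUN peaks, 22.1% overlapped a ChIP-seq peak. The widest ChIP-seq peak, of 6836 bp, lay over Ncan (chromosome 8, 70114011 to 70120846). Others among the widest lay between genes on chromosome 11, over Cilp2, and over Gm13441 and Lamc3. The 5 widest CUT&RUN peaks lay over Dchs1 (26215 bp, chromosome 7, 105760723 to 105786937), Adora2a, Lrrc32, Syt7 and Wnt9b. The overlap fell to 41.8% when the CUT&RUN peaks had to cover 0.5 of the ChIP-seq peak, and to 5.29% when this held in both directions.

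H3K27me3 marked developmental genes in these cells. Of 32968 placed genes, 2998 had a ChIP-seq peak at the 5′ end, 4359 a CUT&RUN peak, and 1963 (5.95%) both, against 396 if the lists were independent. Both lists marked 45 of 105 developmental transcription factors (odds ratio 12.1, Fisher's exact test adjusted over the lists, p = 4.40e-26) and 17 of 38 Hox genes (odds ratio 12.9, p = 1.80e-10). By Fisher's exact test, they also marked 7 of 20 neuroectoderm genes (adjusted p = 0.00102) and 5 of 18 fibroblast genes (adjusted p = 0.0249). No other list passed the threshold. These tests count genes as independent, but Hox genes lie in clusters where neighbours can share a peak. The p for Hox genes may therefore be too small. In the Hoxb cluster (chromosome 11, 96194316 to 96368256) 8 of 10 genes were marked by both, against 3 of 11 in Hoxa, 2 of 9 in Hoxc and 4 of 8 in Hoxd. ChIP-seq peaks covered 28.1% of Hoxb, against 20.6% of Hoxa, 16.6% of Hoxc and 18.9% of Hoxd. CUT&RUN peaks did not set Hoxb apart, with 28.9% of Hoxb, 29.2% of Hoxa, 8.22% of Hoxc and 31.2% of Hoxd covered.

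**Figure D3:**
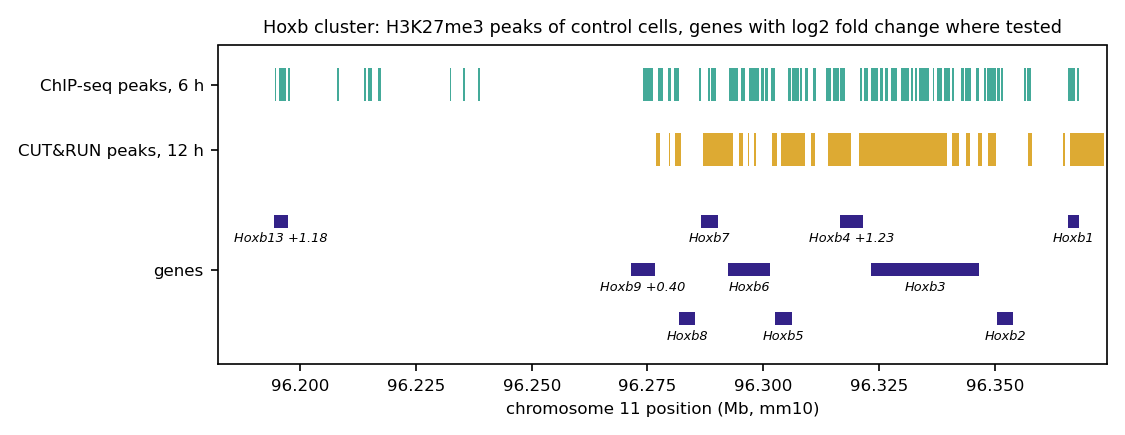
Map of the Hoxb cluster on chromosome 11 (position in Mb, mm10) with the H3K27me3 peaks of control cells by ChIP-seq (green, 56 peaks) and CUT&RUN (yellow, 19 peaks) and the genes (blue). Numbers beside gene names are log2 fold changes with auxin, given for the 3 genes that passed the expression filter.

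Among 512 tested genes marked by H3K27me3 in control cells, 93 rose with auxin, 18 fell and 401 were not called. Their median log2 fold change was 0.29, above that of other genes by camera (p = 6.16e-05) but not with an estimated correlation (p = 0.213 with an estimated correlation). By fry, which sets the marked genes against no change and not against other genes, p was 0.0806. The largest rises were those of Ahrr, Mal, the cartilage collagens Col9a2 (4.23-fold, from 8.38 ± 0.620 to 35.4 ± 3.50 CPM) and Col2a1 (3.72-fold), and Gata2. The largest falls were those of Dab1 (2.98-fold), Esrp1 (2.57-fold), the kinase Lck (2.28-fold), Zmat4 (2.16-fold) and Myrf (1.98-fold, adjusted p = 0.0156). Myrf lost its call without replicate 1 without auxin (0.0537), without auxin replicate 1 (0.0805) and with DESeq2 (0.101), and Esrp1 lost it with DESeq2 (0.0504). Genes marked by ChIP-seq only had a median of 0.24, genes marked by CUT&RUN only a median of 0.18. The share that rose was 23.0% with ChIP-seq only, 16.7% with CUT&RUN only and 18.2% with both. The share that fell was 5.69%, 7.09% and 3.52%, in that order. Of the 12060 genes with neither peak, 49.7% had a positive log2 fold change, against 70.3% of those marked in both lists.

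Of the marked genes 18.2% rose, against 12.8% of other genes (odds ratio 1.51, 95% interval 1.20 to 1.90, Fisher's exact test p = 0.000774). Of the marked genes 3.52% fell, against 15.0% of other genes (odds ratio 0.207, Fisher's exact test p = 1.16e-16). These tests and the interval count genes as independent, although all calls come from the same libraries. They describe these libraries only and leave out correlation among genes. Marked genes were low, with a median of 2.04 CPM against 29.4 CPM for genes with neither peak, and within expression deciles the odds ratio was 1.66 for risers and 0.732 for fallers. The latter was no longer past the threshold (Mantel-Haenszel test over 10 deciles, in place of the exact test, p = 0.199). Random lists matched on expression had a median log2 fold change of 0.16 (central 95%, 0.11 to 0.20). The genes drawn for them included those with a peak in only 1 list. By Fisher's exact test, the higher share of risers among marked genes was lost without replicate 1 without auxin (odds ratio 1.27, p = 0.0850) and without auxin replicate 2 (odds ratio 1.15, p = 0.310), and with only the peaks of larger −log10 q (1.29, p = 0.123).

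**Figure D4:**
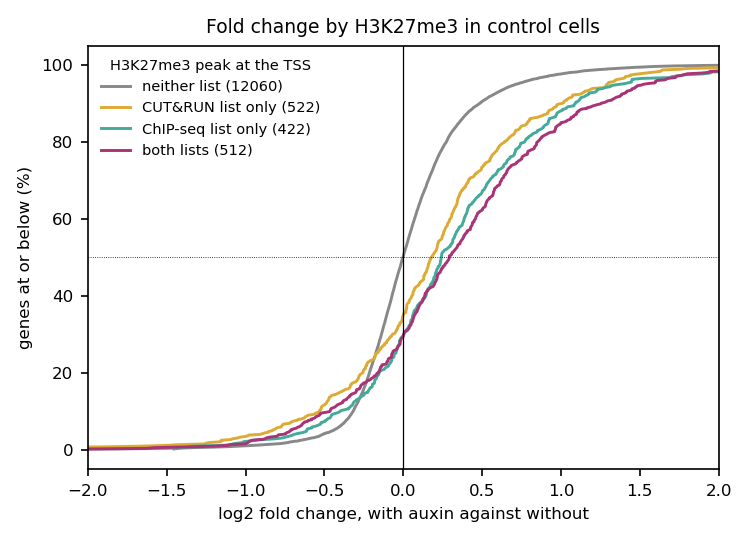
Cumulative share of tested genes (y axis, %) by log2 fold change with auxin (x axis, shown from −2 to 2), split by H3K27me3 peaks at the 5′ end in control cells. The curve of the 512 genes marked in both lists lies to the right, with a median of 0.29, and 49.7% of the 12060 genes with neither peak had a positive value.

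The number of calls differed between tools and when a library was left out. DESeq2 called 880 genes higher and 1442 lower. Without replicate 1 without auxin, 1225 genes were higher and 1257 lower, of which 1118 and 1189 were among the genes called from all 4 libraries.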

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

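The test against a minimum change and the estimated correlation for marked genes were chosen after seeing the data. Counts of higher and lower genes moved to 2972 and 3177 with the replicate number as a block, and to 195 and 106 when tested against a minimum log2 change of 0.5. DESeq2 gave 880 and 1442. Same-numbered libraries deviated together with a correlation of 0.227 over 13522 genes, from 2 pairs. No label says that a number marks a shared culture or day, and 2 pairs are too few to tell, so the numbers were not taken to pair the libraries. The block changed no other call among the counts of lists, the marked genes and Npm1. Left-out libraries gave 1225 to 1705 higher and 1257 to 1914 lower genes, with fewer libraries as part of the cause. Which direction had more calls depended on the scaling, with 47.2% of calls higher in the edgeR result and 54.4% with upper-quartile factors (2024 higher and 1698 lower). With RLE factors the share was 45.9%. DESeq2, which differs from edgeR in more than the scaling, gave 37.9%. RLE and upper-quartile factors and both other filters gave 1734 to 2029 higher and 1698 to 2238 lower genes, and in no setting was a gene called in the opposite direction (0 genes). Npm1 kept its direction and its call throughout, from −0.24 to −0.40 with a library left out. Called gene lists numbered 14, and 0 with an estimated correlation (2 at an unadjusted p under 0.05; fry called 11, all but the Hox, developmental and trophectoderm lists), and 13 to 17 with a library left out.

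Marked genes among the risers had an odds ratio of 1.29 with the peaks of larger −log10 q, and 1.15 to 1.86 with a library left out. Among the fallers the odds ratio was 0.732 within expression deciles, since marked genes are low, and 0.209 to 0.242 with a library left out. The median log2 fold change of marked genes stayed above 0 in all definitions and ran from 0.22 to 0.42 with a library left out. With an estimated correlation it was the same value, 0.29, but not called. ChIP-seq peaks of at least 10 kb were absent (0 peaks), so that definition used the 175 CUT&RUN peaks. The share of ChIP-seq peaks overlapped was 41.8%, 5.29% and 47.5% when 0.5 of the peak, 0.5 of both peaks, or only peaks of larger −log10 q were required, the last in both lists. Against the whole CUT&RUN list, the share was 43.7% in the lowest and 61.3% in the highest set of ChIP-seq peaks when these were split by −log10 q into 4 equal sets. Lists called in peaks numbered 11 with a peak in either list and 12 with a window of 5 kb, against 4, and the cause was not tested. Both larger counts include the G1/S, G2/M, ribosomal protein and ribosome biogenesis lists, which were marked less often than other genes, while the 4 were marked more often. Among 102 named genes besides Npm1, none reversed under the alternatives (0 genes). With a library left out, 4 to 9 lost their call, and 11 of 100 did with DESeq2. Low counts limit the marked genes, whose median was 2.04 CPM.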

Other observations

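Tests of AhR targets against NRF2 targets, of untagged cells, of Wnt targets as a sign of inhibitor strength, and the split of the developmental lists by mark were chosen only after the results were seen, and tests on random lists, except that of marked genes matched on expression, after the fold changes were seen. Genes given below without a value were also named after their values were seen. Of 31 p53 targets, 15 rose, 3 fell and 13 were not called (17 and 5 adjusted over the list alone). The cell cycle inhibitor Cdkn1a rose 1.57-fold and Plk2 1.62-fold, while Pmaip1 fell 1.43-fold, Gtse1 1.20-fold and Pvt1 as well. The list was not called by camera (adjusted p = 0.0683), but was without auxin replicate 1 (0.0339). Of 14 NRF2 targets, 7 rose, 1 fell and 6 were not called (7 and 1 adjusted over the list alone), with Srxn1 up 2.18-fold. The faller, Tkt (adjusted p = 0.0370), lost its call without replicate 1 (0.0888) or 2 (0.165) without auxin, without auxin replicate 1 (0.173) and with upper-quartile factors (0.0801). Camera did not call this list (adjusted p = 0.0866), but did without auxin replicate 2 (0.0137) and without replicate 1 without auxin (0.0494). Of 15 primitive endoderm genes, 6 rose and 9 were not called (7 adjusted over the list alone), including Lamb1 (1.22-fold) and Dab2 (1.81-fold) (camera adjusted p = 0.118, and 0.0475 without auxin replicate 1). Of 13 mesendoderm genes, 5 rose, 2 fell and 6 were not called (5 and 2 adjusted over the list alone). Nodal (1.41-fold), Gsc (2.32-fold, lost with DESeq2 at 0.0606), Cdx1, Wnt3 and brachyury rose, and Eomes (2.78-fold) and Evx1 (2.20-fold) fell (adjusted p = 0.448). Of 12 neuroectoderm genes, 2 rose, 5 fell and 5 were not called (2 and 5 adjusted over the list alone), with Gbx2 down 1.54-fold, Zic5, Sox1 and Olig2 also down and Nes up 1.58-fold (list adjusted p = 0.347). The other riser, Tubb3 (adjusted p = 0.0443), lost its call without replicate 1 (0.306) or 2 (0.0564) without auxin, without auxin replicate 1 (0.136) or 2 (0.0676), and with DESeq2 (0.192).

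Of 28 targets of the integrated stress response, 3 rose, 7 fell and 18 were not called (4 and 9 adjusted over the list alone). Atf3 rose 2.05-fold, as did Gdf15 and Nupr1 by other amounts, and the amino acid transporter Slc7a3 fell 3.31-fold. Nupr1 (adjusted p = 0.0177) lost its call without replicate 2 without auxin (0.0849), without auxin replicate 2 (0.151) and with DESeq2 (0.143). The list was not called (camera adjusted p = 0.347), and its median of −0.07 and test had the opposite sign to its mean of 0.03. Of 20 chaperone genes of the heat shock and unfolded protein responses, 4 rose, 3 fell and 13 were not called (5 and 3 adjusted over the list alone). The endoplasmic reticulum chaperones Hsp90b1 (1.29-fold) and Calr (1.22-fold) rose with Pdia4 and Hspa1a, and Hspa8 (1.22-fold) and the mitochondrial Hspd1 (1.19-fold) fell with Hspe1 (adjusted p = 0.645). Of 21 sterol synthesis genes, 1 rose, 4 fell, including Lss (1.23-fold), Idi1 and Sqle, and 16 were not called (1 and 4 adjusted over the list alone; adjusted p = 0.448). Of 26 imprinted genes, 1 rose (Igf2r, 1.22-fold), 4 fell, namely Zdbf2 (1.70-fold), Grb10 (1.54-fold), Snrpn and Ddc, and 21 were not called (1 and 3 adjusted over the list alone), with a positive median of 0.10 against a negative mean of −0.02 and a test below other genes (adjusted p = 0.767). Of 13 interferon response genes, the RNA sensor Ddx58 fell 4.37-fold, 1 rose (Xaf1) and 11 were not called (0 rose and 1 fell adjusted over the list alone; adjusted p = 0.448). Xaf1 (adjusted p = 0.0363) lost its call without replicate 2 without auxin (0.139), without auxin replicate 1 (0.254) and with DESeq2 (0.128), and the list's median of 0.18 had the opposite sign to its mean of −0.01. Of 11 fibroblast markers, Pdgfrb rose 2.73-fold, Vim fell 1.25-fold and 9 were not called (1 and 1 adjusted over the list alone; adjusted p = 0.836). Of 17 germline genes, 1 rose (Dazl, adjusted p = 0.0185, lost without replicate 2 without auxin at 0.0812, without auxin replicate 1 at 0.0833 and with DESeq2 at 0.115) and 16 were not called (0 adjusted over the list alone; list adjusted p = 0.118, and 0.0379 without auxin replicate 1). Of 22 genes typical of 2-cell embryos, edgeR and DESeq2 called 0, and 1 had an unadjusted p under 0.05. Their median was −0.03, and −0.43 without auxin replicate 2, where camera placed the list below other genes (adjusted p = 0.000370). The median was −0.24 without replicate 1 without auxin (adjusted p = 0.0434), but 0.27 without auxin replicate 1 and 0.24 without replicate 2 without auxin.

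DESeq2 called fewer risers in several of these lists, with 9 p53 targets, 3 primitive endoderm genes, 2 mesendoderm genes, 1 neuroectoderm gene and 1 target of the integrated stress response, and 2 fallers in sterol synthesis. Among the lists that camera did not call, medians lay outside the central 95% of random lists matched on expression for p53 targets (0.16 against a random median of −0.09), NRF2 targets (0.25 against −0.11), chaperone genes (0.06 against −0.09) and neuroectoderm genes (−0.22, with all but 43 of 10000 random lists above it).

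H3K27me3 peaks were sparse on the X chromosome, at 0.287 per Mb by ChIP-seq and 1.38 per Mb by CUT&RUN. The densest chromosome was 11, at 33.6 and 39.4 per Mb, and ChIP-seq also gave 32.5 per Mb on chromosome 8. Chromosome 11 also held the most genes per Mb (19.9), and copy number, which can change how many peaks are called, was not analysed here. Median log2 fold changes of RNA by chromosome lay between −0.03 on chromosome 14 and 0.04 on chromosome 6.

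Genes with H3K27me3 in control cells had a median log2 fold change of 0.29 with auxin, a shift not called with an estimated correlation (p = 0.213), with a fry p of 0.0806 against no change. More genomic DNA in the auxin libraries is argued against, since 1408 silent olfactory and vomeronasal receptor genes gained only 0.398% of what the tested marked genes gained in counts scaled to gene length and library size. A trend with expression level may explain part of the size and is argued against as the whole cause. The median lay above all 10000 lists matched on expression (random median 0.16) and all 10000 matched on expression and length (0.19). The genes drawn included those with a peak in only 1 list (medians of 0.24 with ChIP-seq only and 0.18 with CUT&RUN only). The random medians therefore do not measure an expression trend alone. The random lists drew genes one by one from the fit of all 4 libraries. They leave out correlation among marked genes (estimated at 0.0575) and the spread between libraries, so the size of any remainder is uncertain. Release of Polycomb repression after NPM1 loss is an untested hypothesis for any remainder, and H3K27me3 with auxin was not analysed here. An effect of the auxin compound itself cannot be told apart from NPM1 loss for these or any other genes. None of the analysed auxin libraries came from cells without the degron. Medians were 1.10 for 5 Hox genes and 0.67 for 15 other developmental factors marked in both lists, and 0.61 for 18 Hox genes and 0.30 for 40 other factors not marked in both, some of which had a peak in 1 list, a difference that was not tested. Of those marked in both, 3 of 5 Hox genes and 3 of 15 other factors were called higher. Of the rest, 7 of 18 Hox genes and 12 of 40 other factors were called higher, so the calls for other factors did not follow the medians.

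Of 19 MAPK response genes 12 fell with auxin, although all cultures held a MEK inhibitor. A trend with expression and length is argued against, since all 10000 matched lists had a median above that of the list. These lists also drew genes one by one and leave out correlation among the genes of the list. Stronger MEK and GSK3 inhibition in the auxin cultures may contribute and stays open, because Wnt targets, which GSK3 inhibition raises, had a positive median of 0.23 in the same libraries. That Wnt call was weak by camera (adjusted p = 0.0430, and 0.419 with an estimated correlation). It was lost in 3 of the 4 runs with a library left out, with upper-quartile factors and with the filter of at least 1 read. By fry, the Wnt list was called (adjusted p = 0.0119). Wnt targets bear on GSK3 inhibition only, so they cannot decide whether MEK inhibition was stronger. An effect of NPM1 loss, or of the auxin compound, on FGF signalling also remains open and was not tested.

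Of 7 AhR targets 4 rose with auxin, and the auxin compound acting on the receptor, without NPM1 loss, could produce this as well as NPM1 loss could. Both cannot be told apart here, since 0 of the analysed libraries with auxin came from cells without the degron. A general oxidative stress response is argued against as the whole cause. NRF2 targets other than Nqo1 had a median of 0.15 (13 genes), against 2.77 for 6 AhR targets without Nqo1, a value carried by Cyp1a1, Cyp1b1 and Ahrr, since the other 3 (−0.15 to 0.47) were not called and it stays open for them.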
